A study of Arabidopsis thaliana with 24 samples.

How the data were processed

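The series holds 24 samples, 18 for RNA-seq in 6 groups and 6 for ChIP-seq in 2 groups, with 3 samples per group. Groups were taken from the sample labels before the data were examined, as were the comparisons, the tests, the gene lists and the rule for the genes named. RNA was from 14-day whole seedlings and ChIP material from 8-day seedlings fixed with formaldehyde and precipitated with a FLAG antibody, per the labels' protocols. The time from spraying to harvest, the mutant allele and whether the RNA libraries kept the strand are not given in the sources used here.

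RNA-seq values were the whole-number counts per gene that the authors deposited in 1 table of 18430 genes. TopHat2 2.1.0, RSEM 2.1.30, MACS 1.4.3, ChIPseeker and the TAIR10 build are named, with no roles or order, per the submitters' processing notes. Whether the deposited counts were rounded from RSEM estimates is not stated, and they were used as they are. Counting can split reads among similar genes, so values of near-identical paralogs, and of overlapping or antisense genes, are uncertain. The table had 12 per-sample columns whose names matched a sample label, and 6 per-sample columns that matched none and were not used, so both low light groups and every comparison with them are not analysed here. The fit was planned on all 18 RNA samples and was made on 12 samples in 4 groups, which leaves 8 residual degrees of freedom.

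Counts were filtered with filterByExpr by group, which left 18205 genes, scaled by TMM and tested with edgeR's quasi-likelihood F-test (edgeR 4.0.16, robust fit, 1 mean per group) in 5 contrasts: bzip68 against wt in mock and in H2O2 plants, H2O2 against mock in wt and in bzip68, and the difference of those responses. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Errors of log2 fold changes are standard errors derived from the F statistic, and CPM values are means ± SD of 3 samples on TMM-scaled library sizes. Where a group had few counts, ratios of summed counts carry a 95% exact binomial interval, which covers counting error only. Where all libraries of a group were at 0, the fold was set against 3 counts over the group. Replicates were compared pairwise by a chi-square test of their counts, and no pair lay within sampling noise (chi-square per degree of freedom 6.15 to 28.83). Deviations from the group means of same-numbered samples correlated at 0.37, 0.49 and 0.18 between mock and H2O2 bzip68 samples, so for the response of bzip68 the numbers were taken to pair the samples, from the data and not from the labels. The main fit did not use this pairing, which entered only as the block among the alternatives. In no other comparison were all 3 pairs above 0.1.

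There were 16 gene lists: enzymes that handle reactive oxygen species, glutathione S-transferases, oxidative stress responsive genes, heat shock genes, abscisic acid with drought and cold genes, salicylic acid and immunity, jasmonate, photosynthesis, flavonoid and high light, cell wall expansion, auxin and growth, sugar starvation, the clock, root markers, seed storage and group G bZIP factors. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at a preset inter-gene correlation of 0.01 and beside it with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a contrast. Members past 0.05 were counted over all genes and adjusted over the list alone.

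Genes were named by rule. BZIP68 came first in every sample. Then came, per contrast, up to 6 rising and 6 falling genes with a symbol and the largest log2 fold changes among those called, with a mean of at least 5 CPM in the higher group and no overlap between the groups' samples. From each list came up to 4 members with the smallest adjusted p under 0.05, or the 1 with the smallest p where none passed. For the difference of responses it was the 5 smallest adjusted p, where under 0.05. The 10 peaks of the shorter list with the highest score, and peaks at group G factors and at the genes named by size of change, were also named. Genes changed in both genotype comparisons were named in full, some of them without a symbol.

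Peaks were taken from a larger and a shorter list that the authors deposited. The larger was called at a p-value under 1e-05 with GFP-FLAG as the input, and the shorter was limited to adjusted p-values under 1e-30 and to a window around the start of transcription, per the file headers. The peak score is a multiple of the negative log10 of the peak's p-value, per the file headers, and the deposited adjusted p-values were not used as filters, because they rank differently from the scores (Spearman rho 0.02 over the shorter list) and the method behind them is not stated. Whether the 3 samples of each kind were pooled before peaks were called is not stated. Positions and genes are the authors' own on TAIR10. In a check against the TAIR10 reference, 5343 of 5412 nuclear genes assigned a peak were found, all at overlapping positions, and 0 peaks ran past a chromosome end.

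The G-box CACGTG was searched within 100 bp of the centre of each nuclear peak and of a region shifted by 5000 bp, and the shares were compared by Fisher's exact test, two-sided. Changed and unchanged tested genes were compared for an assigned peak by the same test, as were list members against the other nuclear protein-coding genes, the latter with Benjamini-Hochberg adjustment over lists. The comparisons of peaks with the H2O2 responses, and of peaks with the lists, were chosen after seeing the data. Genes are not independent replicates in these tests.

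The statistics were tested on simulated data for the 18205 genes, with 200 changed by known folds. The share recovered depends on how many genes change, so it may differ in contrasts where more or fewer than 200 do. Genes changed 2-fold were recovered in 62.7% of cases for genotype in mock plants, 74.6% for genotype in H2O2 plants, 70.1% and 79.1% for the H2O2 response of wt and bzip68, and 56.7% for the difference of responses, and those changed 1.5-fold in 13.4%, 22.4%, 22.4%, 20.9% and 3.0%. False calls were 5.8%, 7.7%, 3.8%, 5.0% and 9.3% with edgeR, and 12.8%, 16.7%, 11.0%, 14.2% and 17.9% with DESeq2. For genotype in mock plants, camera called 0 of 20 unchanged lists and the 1 shifted list of 20 genes. Genes were simulated independently of each other, so this cannot show how often camera calls lists of correlated genes falsely. The estimated correlation of the real oxidative stress list was 0.48.

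Alternatives planned before the data were examined were DESeq2 1.42.0, RLE factors, no filter, a 2-fold minimum, only the groups of a contrast, the replicate number as a block, no organelle genes, each library left out, fry, other peak sets, and other G-box windows (50 and 250 bp) and shifts (20000 bp). Added after seeing the data were limma voom with library quality weights, a fit without mock bzip68 replicate 2 and H2O2 wt replicate 2, camera with the block and an estimated correlation, list and peak tests with each library left out, and a Mantel-Haenszel odds ratio over 10 strata of expression. Further tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, matplotlib 3.10.9 and bedtools 2.31.1.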

Results

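Seedlings of Arabidopsis thaliana were profiled by RNA-seq, and by chromatin immunoprecipitation followed by sequencing (ChIP-seq), to ask how bZIP68 acts on stress and growth gene expression. bZIP68 is a basic leucine zipper transcription factor of group G, a family that binds the G-box CACGTG, and the series title describes it as redox-sensitive. RNA came from whole 14-day seedlings of the wild type (wt) and of a bzip68 mutant, grown at 125 µmol of light per square metre per second. Plants were sprayed either with a detergent solution (0.01% Triton X-100, the mock treatment) or with 5 mM hydrogen peroxide in that solution (H2O2), a direct oxidative stress, with 3 samples in each of the 4 groups. Seedlings of both genotypes kept at 30 µmol of light were also sampled, and they are not analysed here. The authors' table gave counts for 18430 genes, of which 18205 passed the filter on low counts. Totals ran from 8997073 to 10262992 counts per library. ChIP came from 8-day seedlings, 3 samples expressing bZIP68-FLAG and 3 expressing GFP-FLAG as the control, deposited as lists of peaks. The labels give these seedlings no treatment, so peaks and expression come from plants of different age and treatment. Nothing in the labels says that samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

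Libraries separated by treatment. The first principal component of log2 CPM (a gene's counts scaled to a common library size) held 32.9% of the variance and placed the mock libraries between -38.6 and -20.9 and the H2O2 libraries between 21.6 and 40.0. On the second component, which held 19.0%, mock bzip68 replicate 2 (-42.1) and H2O2 wt replicate 2 (-34.9) stood apart from the other libraries, which lay between -15.0 and 29.7. H2O2 wt replicate 2 also had 0.0121% of its counts in chloroplast genes, against 1.05% to 1.54% in the others.

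BZIP68 itself (AT1G32150, chromosome 1, 11565494 to 11568645, TAIR10) was almost without counts in the mutant. Mock wt libraries had 74, 82 and 102 counts and mock bzip68 libraries 2, 1 and 1, while H2O2 wt libraries had 87, 93 and 70 and H2O2 bzip68 libraries 2, 0 and 2. Summed over groups, the level was 62.5-fold lower in bzip68 after mock treatment (95% counting interval 24.1 to 231) and 56.5-fold lower after H2O2 (21.8 to 209). The log2 fold change was -5.84 ± 0.38 (SE, n = 3 per group) in mock plants, with an adjusted p of 2.75e-07 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). H2O2 itself left no detectable change of BZIP68 in the wild type, at -0.15 ± 0.21 (edgeR, Benjamini-Hochberg adjusted p = 0.75).

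The question put by comparing the genotypes is which genes depend on bZIP68, and 8 genes besides BZIP68 changed in bzip68 under both treatments, 3 higher and 5 lower. NDL2 (AT5G11790), an N-MYC downregulated-like protein, fell from 154 ± 6.36 to 2.72 ± 1.02 CPM (SD, n = 3) in mock plants and from 102 ± 8.9 to 1.7 ± 0.465 CPM in H2O2 plants. MRD1 (AT1G53480), named for its low expression in the mto1 methionine mutant, rose from 0.28 ± 0.0508 to 32.5 ± 5.56 CPM in mock plants, a 115-fold difference (95% counting interval 58.0 to 267), and was 263-fold higher after H2O2 (102 to 968). HEI10 (AT1G53490), a RING protein of meiotic crossovers, rose 17.3-fold and 12.8-fold under mock and H2O2. SADHU3-2 (AT3G42658), a non-coding Sadhu retrotransposon annotated as a pseudogene, rose from 0.28 to 8.81 ± 2.09 CPM in mock plants and from 0.293 to 6.86 CPM after H2O2. ENT1 (AT1G70330), an equilibrative nucleoside transporter, was 7.89-fold and 8.51-fold lower, and its neighbour AT1G70340 was 3.72-fold and 2.77-fold lower. AT3G05060, a NOP58-like nucleolar protein, was 5.45-fold and 5.30-fold lower. AT4G16870, annotated as a pseudogene, was 2.42-fold and 2.70-fold lower.

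The log2 fold changes of these genes in mock and H2O2 plants were -5.80 ± 0.21 and -5.89 ± 0.22 (SE, n = 3 per group) for NDL2, 6.79 ± 0.28 and 7.90 ± 0.31 for MRD1, and 4.12 ± 0.15 and 3.68 ± 0.14 for HEI10. The highest adjusted p among the 8 was that of AT4G16870, 0.0476 in mock and 0.0419 in H2O2 plants, and the next was 0.00128, for AT1G70340 after H2O2 (edgeR quasi-likelihood, Benjamini-Hochberg). NDL2 lies on chromosome 5 (3799408 to 3803216), SADHU3-2 on chromosome 3 (14749400 to 14750294), AT3G05060 on chromosome 3 (1412867 to 1416056) and AT4G16870 on chromosome 4 (9483955 to 9488397). MRD1 (chromosome 1, 19963047 to 19964712) overlaps HEI10 (19963267 to 19966952) by 1446 bp on the opposite strand. ENT1 (chromosome 1, 26502909 to 26504619) overlaps AT1G70340 (26503961 to 26506672) by 659 bp. No source states that counting used strand, so the values of MRD1 and HEI10, and of ENT1 and AT1G70340, are uncertain. Those of AT3G05060 are uncertain because it has a close paralog. The labels give 1 mutant line and not its allele. Chance would give 0.016 genes called in the same direction in both comparisons, which share no libraries, against 9 observed with BZIP68 included. AT4G16870 lost its call in the mock comparison without mock wt replicate 1 or 2 or mock bzip68 replicate 1 or 3 (log2 fold change -1.46 to -1.06 over all 6 such fits), and in the H2O2 comparison without any 1 of its 6 libraries (-1.56 to -1.22).

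**Figure D1:**
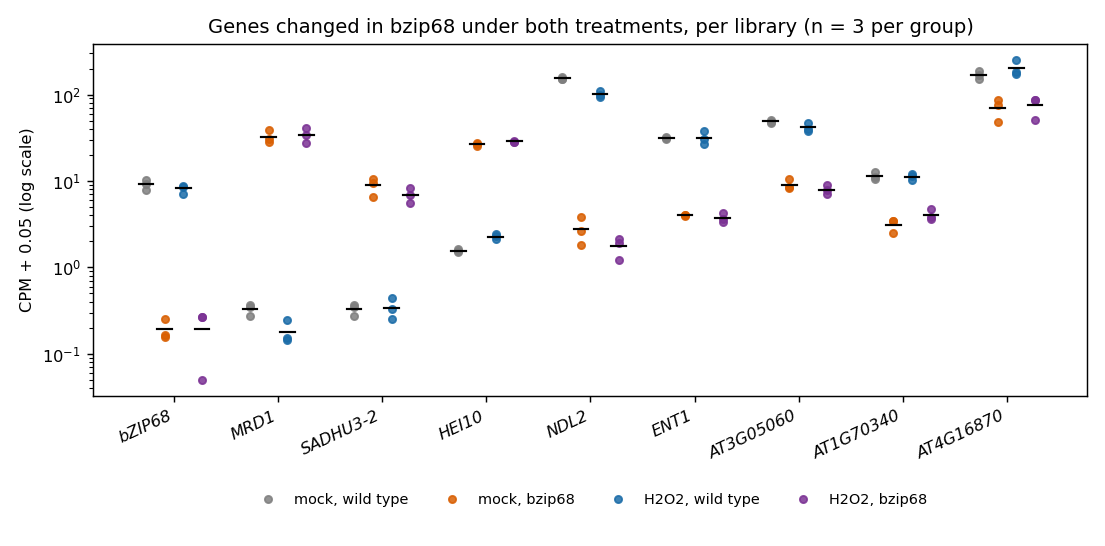
Expression per library (CPM plus 0.05, log axis) of BZIP68 and the 8 other genes that changed in bzip68 under both treatments, by group, with points for single libraries. BZIP68 is at 7.10 CPM or more in each wt library and at 0.218 CPM or less in each bzip68 library.

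After mock treatment, most genes that respond to oxidative stress and most of salicylic acid and immunity had negative log2 fold changes in bzip68 against the wild type, list calls that did not hold with an estimated correlation between genes. Of the 37 measured oxidative stress genes, 34 had negative log2 fold changes, with a median of -0.82. By edgeR 0 passed over all genes, with 21 lower at an unadjusted p under 0.05, against 8 lower by DESeq2 and 14 by limma voom, and 17 were lower adjusted over the list alone. AOX1A, the alternative oxidase of mitochondria, led the list at 159 ± 70.7 CPM in wt and 58.2 ± 5.94 in bzip68 (SD, n = 3; edgeR, Benjamini-Hochberg adjusted p = 0.0745). Of the 19 salicylic acid and immunity genes, 18 were negative (median -0.65, also with PR1, at 0 counts in bzip68, set to its bound, and mean -1.23), 1 was lower over all genes by edgeR, 3 by DESeq2, 7 by limma voom, 10 at an unadjusted p under 0.05 and 8 adjusted over the list alone. The 1 called by edgeR was SAG13, a senescence-associated dehydrogenase, which fell from 6.41 ± 1.37 to 1.91 ± 0.491 CPM. Root markers lay higher, with 12 of 14 positive and a median of 0.48. By edgeR 0 of them passed over all genes (CASP1, of the Casparian strip, 0.57 ± 0.15, Benjamini-Hochberg adjusted p = 0.171), with 7 higher at an unadjusted p under 0.05, 2 by DESeq2, 5 by limma voom and 4 adjusted over the list alone. The libraries behind these lists were not alike, since mock bzip68 replicate 2 is the one that stood apart on the second principal component. Limma voom gave the highest weights to mock bzip68 replicate 3 (3.54) and mock wt replicate 1 (2.66), against 0.35 to 0.78 for the other mock libraries.

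The camera test with a preset correlation of 0.01 called the oxidative stress list (Benjamini-Hochberg adjusted p = 1.58e-15), salicylic acid and immunity (1.56e-09), root markers (9.74e-05), heat shock genes (0.0287, median -0.27, 16 of 21 negative, HSP17.6II -1.39 with edgeR adjusted p = 0.426) and group G bZIP factors (0.0121). Group G holds BZIP68, the 1 member that fell of 5, so its median was -0.10 against a mean of -1.22. None of these list calls held with an estimated correlation (camera adjusted p = 0.254, 0.147, 0.148, 0.919 and 0.254 with an estimated correlation, in the same order). By fry, which tests each list on its own, salicylic acid (adjusted p = 0.014), root markers (0.0373) and group G (0.00416) passed. Oxidative stress (fry adjusted p = 0.0842) and heat shock (0.721) did not. The heat shock call was lost without mock wt replicate 1 (camera adjusted p = 0.272), mock bzip68 replicate 1 (0.0562) or mock bzip68 replicate 2 (0.368), and the group G call without mock wt replicate 1 (0.06) or mock bzip68 replicate 2 (0.0761). Lists that did not pass camera at the preset correlation were glutathione S-transferases (median -0.03, adjusted p = 0.212), enzymes that handle reactive oxygen species (-0.05, 0.441), abscisic acid, drought and cold genes (-0.04, 0.425), jasmonate (-0.15, 0.814), photosynthesis (0.01, 0.425), flavonoid and high light (0.06, 0.814), cell wall expansion (0.20, 0.377), auxin and growth (-0.05, 0.425), sugar starvation (0.02, mean -0.13, 0.846) and the clock (-0.03, 0.846). The glutathione S-transferase list passed without mock wt replicate 1 (0.00505) and sugar starvation without mock wt replicate 3 (0.0333). Of the 8 seed storage genes listed, 0 were measured.

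**Figure D2:**
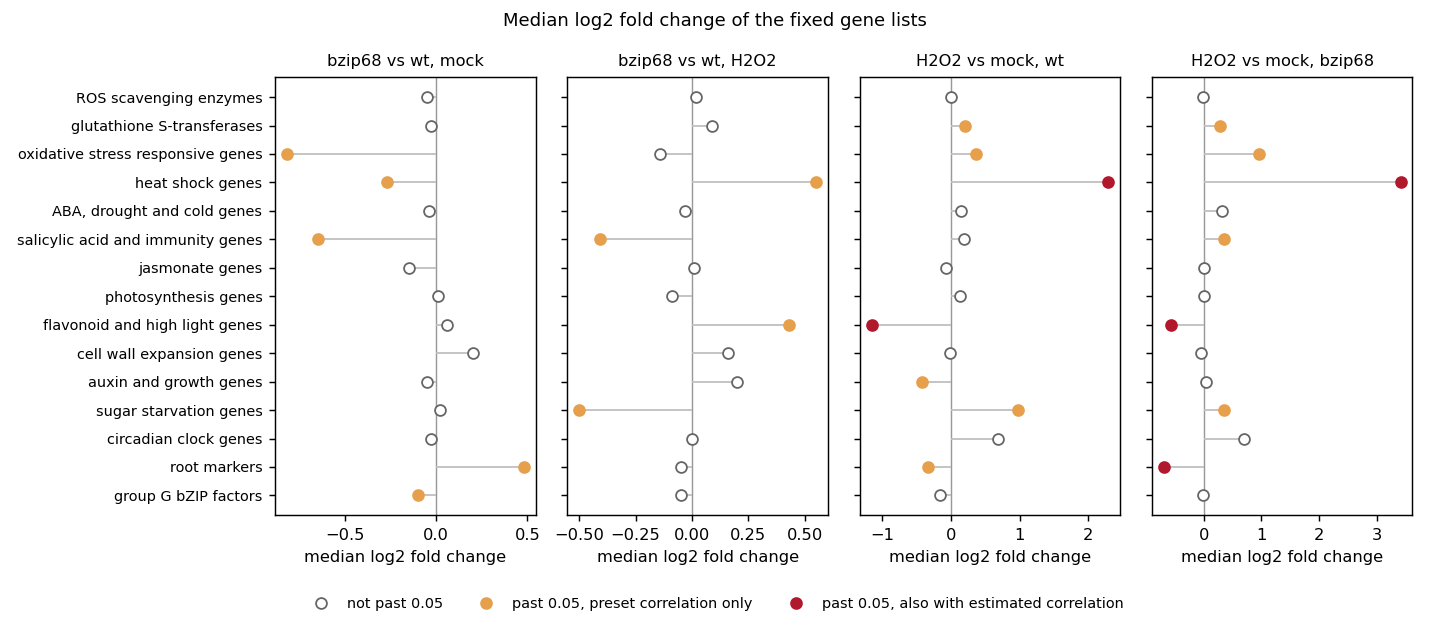
Median log2 fold change of 15 gene lists in the comparisons of genotype (bzip68 against wt, mock and H2O2) and of treatment (H2O2 against mock, wt and bzip68). Colours mark lists past 0.05 in camera at the preset correlation only, and those also past it with an estimated correlation, with the heat shock list at 2.29 in wt and 3.41 in bzip68.

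In all, 39 genes differed between bzip68 and wt after mock treatment, 8 higher and 31 lower (edgeR quasi-likelihood, Benjamini-Hochberg), of which 6 and 21 changed at least 2-fold. ARP9, a nuclear actin-related protein, rose 1.83-fold, from 11.9 to 21.7 CPM. Among those that fell were the ethylene response factor ERF71 (9.29 ± 5.32 to 1.1 ± 0.276 CPM, SD, n = 3), the touch-inducible calmodulin-like TCH3 (415 ± 92.9 to 164 ± 12.7), the cell wall enzyme XTH18 (178 ± 42.2 to 82.4 ± 15.2) and the glutathione S-transferase GSTF6 (99.6 ± 19.5 to 54.3 ± 2.1). Their log2 fold changes were -3.07 ± 0.55 for ERF71, -1.34 ± 0.23 for TCH3, -1.11 ± 0.20 for XTH18, -0.87 ± 0.15 for GSTF6 and -1.73 ± 0.31 for SAG13, with adjusted p from 0.0367 to 0.0465 (edgeR quasi-likelihood, Benjamini-Hochberg). The count depended on single libraries, with 122 genes without mock wt replicate 3, 11 without mock wt replicate 1, 8 without mock wt replicate 2 and 9 without mock bzip68 replicate 3. It was 215 with DESeq2, 843 with limma voom and library weights, 73 without the libraries that stood apart and 17 with only these 6 libraries in the fit. The limma voom fit leaned on mock bzip68 replicate 3 and mock wt replicate 1, by their weights (3.54 and 2.66). With 1 library left out, TCH3, ERF71 and XTH18 passed only without mock wt replicate 3 (log2 fold changes of -1.5, -3.44 and -1.29 at the lowest over the 6 fits). ARP9 lost its call without mock wt replicate 1 or 2 or mock bzip68 replicate 3 (0.76 to 0.98 over the 6 fits). SAG13 lost its call without mock wt replicate 1 or 2 or mock bzip68 replicate 2 or 3 (-1.96 to -1.58), and GSTF6 without mock wt replicate 2 or mock bzip68 replicate 3 (-1.01 to -0.74).

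**Figure D3:**
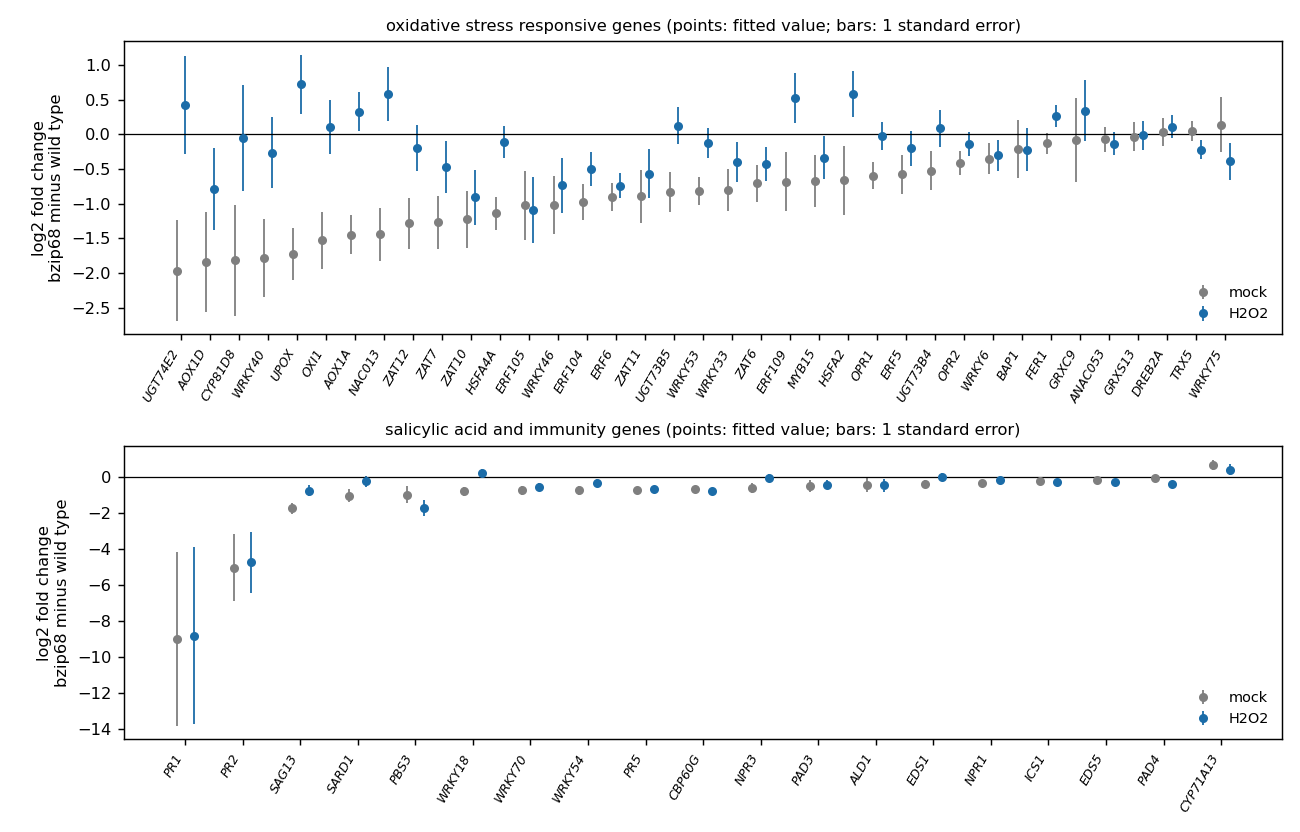
Log2 fold change of bzip68 against wt for each measured member of the oxidative stress list and of the salicylic acid and immunity list, in mock and in H2O2 plants, with bars of 1 SE. In mock plants 34 of 37 and 18 of 19 members lie below 0, and PR1 had 0 counts in bzip68, so its plotted value is a fitted one and no bound.

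After H2O2, most heat shock and flavonoid genes had positive log2 fold changes in bzip68 against the wild type and most sugar starvation and salicylic acid genes negative ones, list calls that did not hold with an estimated correlation between genes. Heat shock genes were positive in 20 of 21 cases, with a median of 0.55 (HSP17.6C 1.04, edgeR adjusted p = 0.109). By edgeR 0 passed over all genes, with 11 higher at an unadjusted p under 0.05, against 3 by DESeq2 and 2 by limma voom, and 10 were higher adjusted over the list alone. Flavonoid and high light genes were positive in 17 of 19 cases, with a median of 0.43 (UF3GT 1.41, edgeR adjusted p = 0.185), 0 passing over all genes by edgeR or limma voom, 2 by DESeq2, 11 at an unadjusted p under 0.05 and 11 adjusted over the list alone. All 10 sugar starvation genes were negative, with a median of -0.50, and SEN1, a dark- and senescence-induced gene, fell from 24.2 ± 0.877 to 6.01 ± 2.41 CPM (SD, n = 3), the 1 member lower over all genes by edgeR and by limma voom, against 2 by DESeq2, 6 at an unadjusted p under 0.05 and 6 adjusted over the list alone. Salicylic acid and immunity genes were negative in 16 of 19 cases (median -0.41, mean -1.05, CBP60G -0.75 with edgeR adjusted p = 0.168), 0 passing over all genes by edgeR, 1 by DESeq2 and by limma voom, 7 at an unadjusted p under 0.05 and 3 adjusted over the list alone. H2O2 wt replicate 2, the library with few chloroplast counts, is among the 3 wild-type samples of each of these values.

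Camera called flavonoid and high light (adjusted p = 7.81e-09), sugar starvation (5.84e-08), heat shock (9.78e-08) and salicylic acid and immunity (2.74e-06), and each of these calls held in every fit that left out 1 library. With an estimated correlation none did (camera adjusted p = 0.0755, 0.152, 0.213 and 0.152 with an estimated correlation). By fry, flavonoid (adjusted p = 0.00758), sugar starvation (0.0292) and salicylic acid (0.0489) passed, and heat shock (0.0987) did not. Group G, which holds BZIP68, also passed by fry (0.00758). Lists that missed the threshold included oxidative stress (median -0.14, camera adjusted p = 0.0642), photosynthesis (-0.09, 0.0616), cell wall expansion (0.16, 0.0616), auxin and growth (0.20, 0.0616), jasmonate (median 0.01, mean -0.15, 0.99) and root markers (median -0.05, mean 0.07, 0.699). Of these, oxidative stress passed without H2O2 wt replicate 3 (0.00709) or H2O2 bzip68 replicate 3 (0.000113), photosynthesis without H2O2 wt replicate 2 (0.000984) or H2O2 bzip68 replicate 1 (0.000829) or 2 (0.0311), auxin without H2O2 wt replicate 1 (0.00247) or H2O2 bzip68 replicate 2 (0.045) or 3 (0.0214), and cell wall expansion without H2O2 bzip68 replicate 1 (0.0227) or 3 (0.0108). The abscisic acid list (median -0.03, 0.604) passed without H2O2 wt replicate 3 (0.0398), and group G (-0.05, 0.152) without H2O2 bzip68 replicate 1 (0.0475).

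In H2O2 plants 13 genes differed between the genotypes, 5 higher and 8 lower (edgeR quasi-likelihood, Benjamini-Hochberg). Apart from those changed under both treatments they included SEN1 (-2.01 ± 0.29 log2, 4.03-fold lower), the receptor-like kinase FRK1, a marker of early immune signalling (-1.84 ± 0.28, 7.15 ± 1.64 to 1.99 ± 0.822 CPM), and the ribosomal protein RPL23AB (0.62 ± 0.11, 57.6 ± 0.53 to 88.6 ± 2.04 CPM), each with SE on the log2 scale and n = 3 per group. Reads of RPL23AB can be shared with its paralog RPL23AA, so its value is uncertain. The remaining gene, AT3G13230, a KH-domain protein without a symbol and named after its value was seen, was 0.66 log2 units higher. The adjusted p was 0.0122 for SEN1 and FRK1 and 0.0395 for RPL23AB (edgeR quasi-likelihood, Benjamini-Hochberg). The count was 8 without H2O2 wt replicate 1 or 3, 72 with DESeq2, 31 with only these 6 libraries, 26 with limma voom and 27 without the libraries that stood apart. SEN1 lost its call without H2O2 wt replicate 1 or 3 or H2O2 bzip68 replicate 2 (-2.27 to -1.72 over the 6 fits), FRK1 without H2O2 wt replicate 1 or 3 or H2O2 bzip68 replicate 1 or 3 (-2.23 to -1.67), and RPL23AB without any 1 of the 6 libraries (0.61 to 0.64).

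In the wild type, small heat shock proteins and evening genes of the clock were higher in H2O2 than in mock plants. Flavonoid, high light and morning-expressed genes were lower. The labels give no time of harvest. For genes under clock control, H2O2 and another time of day at harvest cannot be told apart. Heat shock genes rose in 14 of 21 cases, with a median log2 fold change of 2.29. HSP17.6A rose 28.1-fold, from 0.709 to 20.2 CPM, HSP17.6C 34.2-fold (95% counting interval 19.4 to 66.7) and HSP90.1, a cytosolic chaperone, from 19.6 to 127 CPM. COR27, a cold- and clock-regulated gene, rose from 2 to 210 counts summed over 3 libraries, 97.4-fold (26.6 to 809). FKF1, a blue light receptor that sets flowering time, rose 20.3-fold, from 2.42 ± 0.33 to 49.6 ± 3.05 CPM (SD, n = 3).

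Of 12 clock genes 6 rose and 5 fell, in plants whose time of harvest the labels do not give. ELF4 (3.70 log2), PRR5 (27.6 to 202 CPM) and LUX (1.85) rose, while the morning factor LHY fell from 21.5 ± 2.01 to 2.19 ± 0.104 CPM (SD, n = 3), a log2 fold change of -3.29 ± 0.22 (SE). Flavonoid and high light genes fell in 14 of 19 cases, among them F3H, an early enzyme of flavonoid synthesis (123 to 38.8 CPM), and the early light-induced proteins ELIP1 (-1.76) and ELIP2 (-2.66). Sugar starvation genes rose in 7 of 10 cases, though the list did not pass with an estimated correlation (camera adjusted p = 0.1), with SEN1 going from 4.59 to 24.2 CPM and DIN10 from 354 to 885. Among the enzymes that handle reactive oxygen species 4 rose and 4 fell of 39: the peroxisomal catalase CAT2 fell from 2250 ± 159 to 742 ± 91.9 CPM (SD, n = 3), while CAT3 rose from 1510 to 2670, CAT1 from 33.6 to 95 and the glutathione peroxidase GPX6 from 126 to 214. For these enzymes too, H2O2 and another time of day at harvest cannot be told apart. Oxidative stress genes rose in 8 and fell in 5 of 37 cases, with the transcription factors DREB2A (7.49 to 35.2 CPM) and WRKY75 (2.49 log2) higher and the ferritin FER1 (307 to 109 CPM) lower.

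Among the other lists of the wild-type response, auxin genes had a median of -0.42 and root markers one of -0.33. Glutathione S-transferases rose in 5 and fell in 2 of 28 cases (GSTU12 3.07, GSTU9 -1.76), and abscisic acid, drought and cold genes rose in 7 and fell in 3 of 35 (ADH1 2.43, COR15B 2.11). Salicylic acid and immunity genes rose in 4 of 19 (PAD3 1.54, PAD4 0.73), jasmonate genes rose in 1 (AOC2 0.56) and fell in 1 (JAZ9 -0.64) of 21, and auxin genes fell in 2 of 19 (IAA17 -0.76, IAA19 -0.77). Photosynthesis genes rose in 2 and fell in 3 of 45. LHCB1.4 went from 2410 to 6330 CPM and RBCS1B changed by -0.97 log2, but both belong to families of near-identical copies and are uncertain. Cell wall expansion genes rose in 2 and fell in 2 of 18 (EXPA11 0.85, XTH18 -1.42), and root markers fell in 4 of 14 (NRT2.1 -0.85, IRT1 -1.5). Of 5 group G factors, 0 passed by edgeR or DESeq2 (GBF3 -0.55, edgeR adjusted p = 0.101), with 2 lower by limma voom and at an unadjusted p under 0.05.

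Over all genes, 1773 differed between H2O2 and mock plants of the wild type, 913 higher and 860 lower after H2O2. Of these, 361 and 294 changed at least 2-fold (edgeR quasi-likelihood, Benjamini-Hochberg). Adjusted p was 4.86e-06 for COR27, 1.74e-06 for HSP17.6A, 1.4e-10 for FKF1, 3.46e-07 for LHY and 2.44e-05 for CAT2 (edgeR, Benjamini-Hochberg). The lists called by camera, with counts adjusted over the list alone, were heat shock (adjusted p = 1.18e-20, 17 higher), flavonoid and high light (1.08e-15, 18 lower), sugar starvation (1.66e-08, 10 higher), auxin (0.00609, 4 lower), root markers (0.00798, 4 lower), oxidative stress (0.0217, 10 higher and 5 lower) and glutathione S-transferases (0.0488, 8 higher and 4 lower). With an estimated correlation heat shock (0.039) and flavonoid (0.0141) passed, and sugar starvation, auxin, root, oxidative stress and glutathione S-transferase lists did not (adjusted p = 0.1, 0.577, 0.282, 0.623 and 0.577 with an estimated correlation). The oxidative stress call was lost without mock wt replicate 3 (camera adjusted p = 0.509) or H2O2 wt replicate 2 (0.0965), and that of glutathione S-transferases without mock wt replicate 1 (0.215) or H2O2 wt replicate 1 (0.209), while photosynthesis passed without H2O2 wt replicate 2 (0.00847) or mock wt replicate 2 (0.0326). Salicylic acid and immunity (camera adjusted p = 0.0819) passed without mock wt replicate 2 (0.025) or H2O2 wt replicate 2 (0.0182), and abscisic acid (0.135) without H2O2 wt replicate 3 (0.0127). The clock list, with members going both ways, did not pass camera (median 0.69, camera adjusted p = 0.135) but passed by fry (adjusted p = 0.00128). The enzymes of reactive oxygen species passed neither camera (median 0.01, mean -0.04, adjusted p = 0.749) nor fry (0.851). Fry also passed heat shock (adjusted p = 5.23e-05), flavonoid (3.61e-05), sugar starvation (0.00128) and root markers (0.0185). It did not pass auxin (fry adjusted p = 0.148), oxidative stress (0.299) or glutathione S-transferases (0.16). The gene count was 1126 without mock wt replicate 3, 1145 without mock wt replicate 1 and 2938 with limma voom. LEA3, a late embryogenesis abundant protein (-3.61 ± 0.72), and IAA17 lost their calls without H2O2 wt replicate 3 (LEA3 -2.84 to -4.21 over the 6 fits). AOC2 lost its call without mock wt replicate 3 and RBCS2B (-0.52) without H2O2 wt replicate 2. A further 9 of the 61 named genes that passed, among them PAD4, JAZ9, IAA19 and IRT1, lost theirs in more than 1 of these fits.

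In bzip68, heat shock genes again had the highest median of the lists after H2O2. They rose in 16 of 21 cases, with a median of 3.41. HSP17.6A rose by 6.60 ± 0.41 on the log2 scale (SE, n = 3 per group), HSP17.6II 83.9-fold (95% counting interval 47.8 to 163) and HSP90.1 from 16.9 to 186 CPM. COR27 rose 59.8-fold (23.1 to 221), FKF1 20.4-fold and the calmodulin-like CML37 39.2-fold, while LHY fell from 16.7 to 2.23 CPM. BZIP68 had 4 counts in total in each of the bzip68 groups (-0.01 log2, edgeR adjusted p = 0.998).

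Oxidative stress genes rose in 17 of 37 cases and fell in 1 in bzip68, with DREB2A (2.31), ERF6 (1.65) and the heat shock factor HSFA2 (3.25) higher and FER1 (-1.09) lower. Glutathione S-transferases rose in 8 and fell in 1 of 28 (GSTU4 2.49, GSTU12 2.87), and salicylic acid genes rose in 4 of 19 (PAD3 1.61, WRKY18 1.07). Flavonoid and high light genes fell in 6 of 19 (F3H -0.90, ELIP1 -1.34), root markers fell in 7 of 14 (EXPA7 -1.94, CASP1 -0.93), and sugar starvation genes rose in 2 of 10 (DIN10 0.96). Among the enzymes of reactive oxygen species 4 rose and 2 fell of 39, with CAT2 going from 1970 to 810 CPM. The clock list again had 6 higher and 5 lower of 12 (ELF4 3.44, PRR5 2.63), abscisic acid genes 7 higher and 4 lower of 35 (COR15B 3.02, ABF3 -0.88) and jasmonate genes 1 higher and 2 lower of 21 (MYC2 -0.67). Of the 45 photosynthesis genes 0 passed in edgeR over all genes (RCA -0.56, adjusted p = 0.0552, and passing at -0.55 with the replicate number as a block), with 3 higher and 6 lower at an unadjusted p under 0.05, 1 and 3 by DESeq2 and 2 and 2 by limma voom. A single gene each changed among cell wall expansion (EXPA11 0.60) and auxin genes (GH3.5 -0.75).

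In bzip68, 1346 genes differed between H2O2 and mock plants, 748 higher and 598 lower after H2O2 (edgeR quasi-likelihood, Benjamini-Hochberg). Camera called heat shock (adjusted p = 3.66e-32), oxidative stress (2.39e-11), flavonoid and high light (2.5e-08), root markers (1.76e-07), glutathione S-transferases (0.00279), salicylic acid and immunity (0.00279) and sugar starvation (0.0168). Adjusted over the list alone, heat shock had 20 higher, oxidative stress 19 higher and 1 lower, and flavonoid genes and root markers 9 lower each. Glutathione S-transferases had 11 higher and 3 lower, salicylic acid genes 7 higher and 1 lower, and sugar starvation genes 2 higher. The camera calls of heat shock, flavonoid and root markers held with an estimated correlation (0.0211, 0.0348 and 0.0348), and the others did not (oxidative stress adjusted p = 0.347, glutathione S-transferases 0.43, salicylic acid 0.368 and sugar starvation 0.43 with an estimated correlation). By fry, heat shock (adjusted p = 8.05e-06), root markers (0.000634), flavonoid (0.000655) and oxidative stress genes (0.024) passed. Glutathione S-transferases (fry adjusted p = 0.0392) and salicylic acid (0.0406) also did, and sugar starvation (0.119) did not. The clock list, not called by camera (adjusted p = 0.124), passed by fry (0.000634). With the replicate number as a block and an estimated correlation, root markers did not pass (camera adjusted p = 0.0769), while heat shock (0.0451) and flavonoid genes (0.00892) did. Sugar starvation lost its call without H2O2 bzip68 replicate 2 (camera adjusted p = 0.0932), while auxin (median 0.04, mean -0.17, 0.561) passed without mock bzip68 replicate 2 (0.0139) and abscisic acid (0.31, 0.0879) without mock bzip68 replicate 3 (0.0401). The gene count was 719 without H2O2 bzip68 replicate 3, 791 without mock bzip68 replicate 3, 855 with only these 6 libraries and 2358 with limma voom. With the replicate number as a block it was 1519. Of the 51 named genes that passed, 10 lost the call without 2 or more of the 6 libraries in turn, among them MYC2, GH3.5, EXPA11 and WRKY18.

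Many genes that responded to H2O2 did so in both genotypes. Of the genes that rose, 508 did so in both, against 37.5 for independent lists, and 355 fell in both, against 28.2. Among the 2256 genes changed in either genotype 2111 had the same sign in both, with a correlation across genes of 0.849 (genes are not independent replicates), and the slope of the bzip68 on the wt log2 fold change was 0.81. Over all 18205 tested genes, not chosen for a change, 11440 had the same sign, with a correlation of 0.642 and a slope of 0.63. The test of the difference itself, bzip68 response minus wt response, called 0 genes by edgeR, with 1178 at an unadjusted p under 0.05, against 24 by DESeq2 and 0 by limma voom. It called 26 genes, all with a higher response in bzip68, without mock wt replicate 3, and 1 without mock bzip68 replicate 3 or H2O2 bzip68 replicate 2.

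**Figure D4:**
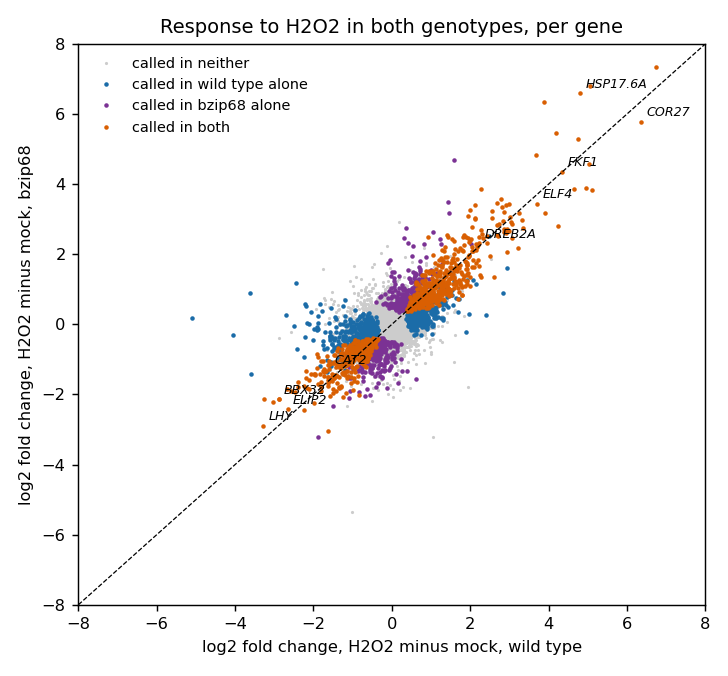
Log2 fold change of H2O2 against mock in wt (horizontal axis) and in bzip68 (vertical axis), with each point a tested gene and colours for the genotype in which it changed. Among the 2256 genes changed in either genotype 2111 have the same sign in both.

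By gene list, the difference of responses passed camera at the preset correlation for 7 lists, and for none with an estimated correlation in the fit without a block. With the replicate number as a block and an estimated correlation, flavonoid and high light genes passed (camera adjusted p = 0.0261). Heat shock genes responded more positively in bzip68, by a median of 0.76 (camera adjusted p = 1.64e-08, and adjusted p = 0.288 with an estimated correlation), as did oxidative stress genes by 0.42 (1.58e-06, 0.579) and flavonoid and high light genes by 0.42 (6.33e-06, 0.262). Sugar starvation genes (-0.36, 2.25e-05, 0.288) and root markers (-0.44, 0.021, 0.389) responded more negatively. Auxin (0.37, 0.0299, 0.743) and photosynthesis genes (-0.12, 0.0299, 0.743) passed narrowly. Root markers lost the call without mock wt replicate 1 (0.0511) or H2O2 wt replicate 1 (0.0535) or 3 (0.0598). Auxin lost it without mock wt replicate 2 (0.0562) or 3 (0.0607), mock bzip68 replicate 2 (0.27), H2O2 wt replicate 2 (0.16) or 3 (0.0589) or H2O2 bzip68 replicate 1 (0.216), and its median was -0.02 without the 2 libraries that stood apart. Photosynthesis lost it without mock wt replicate 1 (0.0875), mock bzip68 replicate 2 (0.197), H2O2 wt replicate 1 (0.116) or 3 (0.181) or H2O2 bzip68 replicate 3 (0.452). Adjusted over the list alone, 3 oxidative stress, 1 heat shock and 2 flavonoid genes were higher, and 2 sugar starvation genes and 1 root marker lower. Of lists that did not pass, 2 cell wall expansion genes and 1 glutathione S-transferase were higher. The lists that did not pass had medians of 0.19 (salicylic acid), 0.11 (glutathione S-transferases), 0.03 (enzymes of reactive oxygen species), 0.01 (clock) and -0.05 (abscisic acid, and cell wall expansion). Salicylic acid (0.279) passed without mock wt replicate 3 (0.0135) and glutathione S-transferases (0.205) without mock wt replicate 1 (0.0175).

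The ChIP-seq peaks address where bZIP68-FLAG binds. The larger of the authors' lists held 5734 peaks on nuclear chromosomes, 10 on the chloroplast and 4 on the mitochondrial genome, assigned to 5424 genes, 96.5% of them annotated to promoters and 81.6% within 1 kb of the start of transcription. The shorter list, made of 892 genes' peaks, had 97.7% within 1 kb, and each of its peaks is in the larger list with the same coordinates. Scores are the authors' own and are used here only to rank peaks within a list. The highest score, 3135.41, belonged to an 88 bp peak at AT3G41768 (chromosome 3, 14197631 to 14197718), annotated as 18S ribosomal RNA, a multi-copy sequence where the assignment is uncertain. Next came AT1G15670 (2258.7, chromosome 1, 5389987 to 5391346), a Kelch repeat F-box protein of the cytokinin response, and the antisense long non-coding RNA AT4G37895 (2101.71, assignment uncertain). DAD1, a phospholipase of jasmonate synthesis, had a score of 1832.44 (chromosome 2, 18478809 to 18480960) and a G-box within 100 bp of the peak centre. The others of the first 10 were SDR2, the purine permease PUP4, the exostosin family gene AT1G68470, TPS11 of trehalose metabolism (chromosome 2, 8107279 to 8108177, 866 bp upstream), CYP86A4 and AT5G43540, with scores from 1817.95 down to 1431.96.

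Group G factors themselves had peaks. BZIP68 (522.39, chromosome 1, 11565955 to 11567202, inside the gene), GBF2 (558.52), GBF3 (489.72) and GBF1 (191.09) had one each, none with a G-box within 100 bp, and BZIP16 had none. At BZIP68 reads from the transgene and from the native locus give the same sequence, so this peak is uncertain. Genes that changed after H2O2 and had a peak included ERF6 (666.3), FER1 (656.62), LHY (598.48), BBX32 (513.09), COR27 (447.28), CML37 (246.86), CAT2 (161.72) and FKF1 (154.68). Of the 8 genes changed in bzip68 under both treatments NDL2 was assigned a peak (114.71), and the other 7 were not.

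The G-box was concentrated at peak centres. It lay within 100 bp of the centre in 1412 of 5734 nuclear peaks of the larger list (24.6%), against 2.39% of regions shifted by 5000 bp (odds ratio 13.3, 95% interval 11.1 to 16.1, Fisher's exact test, two-sided p = 1.08e-302). In the shorter list the share was 32.8% against 2.57% (odds ratio 18.5, 11.9 to 30.0, Fisher's exact p = 6.78e-72). With the larger list parted into 4 groups by score, the share was 33.1% in the group with the highest scores and 26.2% and 21.9% in the next 2, and 249 of 1434 peaks of the group with the lowest scores had a G-box.

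**Figure D5:**
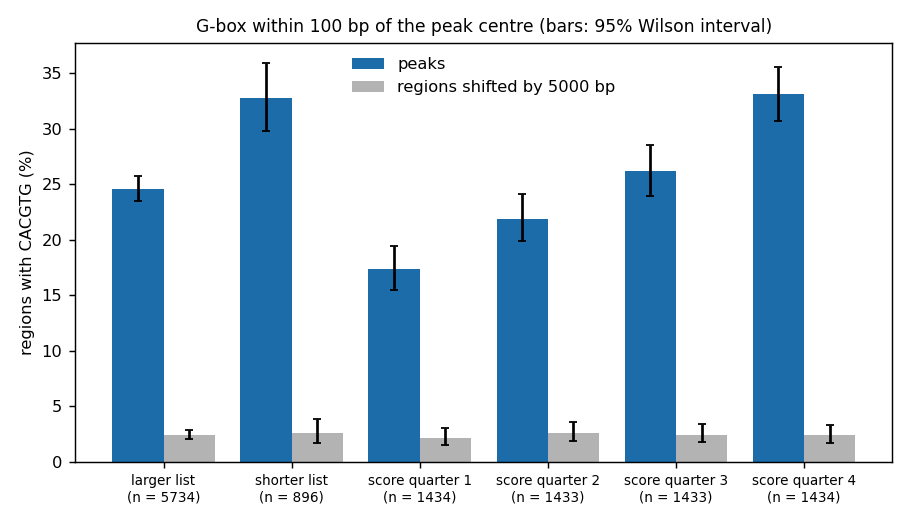
Share of peaks with a G-box within 100 bp of the centre (percent, with 95% Wilson intervals), for both peak lists and for 4 parts of the larger list by score, beside regions shifted by 5000 bp. Peaks of the larger list are at 24.6% and shifted regions at 2.39%.

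Peaks lay at many genes of abscisic acid, drought and cold (27 of 41, 65.9%) and of photosynthesis (29 of 45, 64.4%), against 18.5% of other genes (Fisher's exact test, Benjamini-Hochberg adjusted p = 3.3e-10 and 2.78e-10). Oxidative stress genes (17 of 37, 45.9%, Fisher's exact, adjusted p = 0.000699), sugar starvation genes (6 of 10, 60%, 0.0164) and group G factors (4 of 5, 80%, 0.0164) also had more peaks than other genes (18.6%). The group G count holds the uncertain peak at BZIP68. The other genes here are all nuclear protein-coding genes, also those not tested for expression changes. Against tested genes alone, where 22.6% had a peak, the odds ratio of oxidative stress genes was 2.91 in place of 3.73. Expression level was not allowed for in these list tests. Clock genes (46.2%, exact adjusted p = 0.0573), flavonoid and high light (38.1%, 0.0967), jasmonate (33.3%, 0.155), cell wall expansion (33.3%, 0.202), auxin (30.4%, 0.255), enzymes of reactive oxygen species (29.3%, 0.187), salicylic acid and immunity (21.7%, 0.741), heat shock (16.0%), root markers (14.3%), glutathione S-transferases (12.9%, 0.663) and seed storage genes (12.5%) did not pass.

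Genes that changed with H2O2 carried peaks more often than other tested genes, in the wild type (570 of 1773, 32.1%, against 21.7%, odds ratio 1.71, 95% interval 1.54 to 1.91, Fisher's exact p = 4.46e-22) and in bzip68 (455 of 1346, 33.8%, against 21.8%, odds ratio 1.83, 1.62 to 2.07, exact p = 2.91e-22). The odds ratio was 2.03 for genes that fell and 1.36 for genes that rose in the wild type, and 2.18 and 1.5 in bzip68. For genes that rose in bzip68 it did not pass with the shorter list (1.34, 95% interval 0.93 to 1.87, exact p = 0.1). Of the 39 genes that differed between the genotypes after mock treatment 15 had a peak (38.5%, against 22.6%, odds ratio 2.13, 1.04 to 4.24, Fisher's exact p = 0.0326), and of the 13 after H2O2 2 had one (odds ratio 0.62, 0.0667 to 2.84, exact p = 0.745). The mock value stayed past the threshold with promoter peaks only (2.19, exact p = 0.0199), over expression strata (2.11, Mantel-Haenszel p = 0.0199) and without mock wt replicate 3 (1.73, exact p = 0.00631). With the genes called by DESeq2 it passed but fell to 1.38 (exact p = 0.0405), with 1.52 for genes lower and 0.79 for genes higher in bzip68. It lost its call with the shorter list (2.83, exact p = 0.0643), with peaks above the median score (1.64, 0.216), and with the calls made without mock wt replicate 1 (1.28, 0.721), mock wt replicate 2 (1.14, 1.0), mock bzip68 replicate 1 (1.86, 0.0986) or mock bzip68 replicate 2 (1.31, 0.388), and it was 0.974 without mock bzip68 replicate 3 (1.0).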

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

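The test of root tissue and those of peaks at listed genes below were chosen only after the result was seen, and the other tests of this part were set before it.

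The camera test of the difference itself, bzip68 response to H2O2 minus wt response, at the preset correlation drew attention to 7 gene lists, with medians on the log2 scale. Oxidative stress responsive genes differed by 0.42, heat shock genes by 0.76, flavonoid and high light genes by 0.42 and auxin and growth genes by 0.37. Photosynthesis genes differed by -0.12, sugar starvation genes by -0.36 and root markers by -0.44. With an estimated correlation and no block none of the 7 passed, with camera adjusted p from 0.262 to 0.743.

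For oxidative stress genes the difference of responses goes with a lower starting level in the mutant (both values use the mock libraries), since the median for bzip68 against wt was -0.82 in mock plants and -0.14 in H2O2 plants, and that of salicylic acid and immunity genes was -0.65 and -0.41. A single library as the whole cause is argued against by the oxidative stress median, which was -0.68 at its highest with any 1 of the 6 mock libraries left out. More root tissue of all kinds in the mock bzip68 samples is argued against by the 5 most abundant root markers, which moved apart: 2 were at a log2 fold change of 0 or less (PHO1 -0.04 ± 0.14 and SCR -0.06 ± 0.13) and PYK10 at 0.06 ± 0.13, but CASP1 at 0.57 ± 0.15 and PRP3 at 1.37 ± 0.39, so a change in some root cells stays open. Loss of bZIP68 binding at the listed genes had the value it needs for both lists together. Their members carried a peak more often than other tested genes (odds ratio 2.21, 22 of 56 against 22.6%, Fisher's exact p = 0.00579). Salicylic acid genes alone did not pass (5 of 19 tested, 26.3%, against 22.7%, odds ratio 1.22, exact p = 0.783). Peaks alone do not decide it. Abscisic acid, drought and cold genes (65.9% with a peak) and photosynthesis genes (64.4%) did not pass camera in mock bzip68 (medians -0.04 and 0.01). Those shares are over nuclear protein-coding genes. The peaks are also from 8-day seedlings with no treatment in the labels. A different handling of the mock wild-type plants also stays open and was not tested, as the touch-inducible TCH3 and XTH18 were among the genes higher there, as does an effect of the mutation through other genes.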

How the results depend on the processing

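The fits with limma voom, without the libraries that stood apart and with camera under the block and an estimated correlation, the list, overlap and peak tests with 1 library left out, the odds ratios over expression strata, and all peak tests on the H2O2 responses and on gene lists were chosen only after seeing the data; the other tests were planned. RLE factors, no filter and no organelle genes left each count of changed genes within 1.5 times, and of 75 list medians 0 changed sign with RLE factors or DESeq2 scaling. Changed genes for genotype in mock plants numbered 215 with DESeq2, 17 with only the groups of the contrast, 843 with limma voom and 73 without mock bzip68 replicate 2 and H2O2 wt replicate 2, against 39, of which 39, 13, 39 and 29 were shared. With only those groups 47.1% of calls were higher, against 20.5%. For genotype in H2O2 plants the counts were 72, 31, 26 and 27, against 13. The wt response had 655 genes at a 2-fold minimum and 2938 with limma voom, against 1773, and the bzip68 response 552 and 2358, and 855 with only its groups, against 1346. DESeq2 called 24 genes for the difference of responses, against 0, and 18 in the same direction in both genotype comparisons, against 9. The cause was not tested, except that a 2-fold minimum can only remove calls.

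With 1 library left out, counts ran from 8 to 122 (genotype, mock), 8 to 16 (genotype, H2O2), 1126 to 1544 (wt response), 719 to 1753 (bzip68 response) and 0 to 26 (difference), and genes in both genotype comparisons from 8 to 9. Lists called ran from 3 to 6 for genotype in mock, 5 to 7 in H2O2, 6 to 9 and 6 to 8 for the wt and bzip68 responses and 4 to 7 for the difference. Of 15 named genes called for genotype in mock plants 8 passed in each such fit, as did 8 of 12 in H2O2, 48 of 61 in the wt and 41 of 51 in the bzip68 response. Over all alternatives 2302 values of named genes kept their side of the threshold, 185 lost the call and 31 gained it. Among genes called in the main fit or in the alternative, 0 changed sign. Changes of sign where neither fit called the gene were counted among the 2302.

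Lists called, 5, 4, 7, 7 and 7 (genotype in mock and H2O2, wt and bzip68 response, difference), were 0, 0, 2, 3 and 0 with an estimated correlation, 3 for genotype in mock and 0 for the difference with fry, and 3 for genotype in mock without the libraries that stood apart.

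The replicate number as a block gave 44, 21, 2002, 1519 and 0 changed genes, so the count of 13 for genotype in H2O2 plants became 21, 9 genes in both genotype comparisons, and 7 lists in place of 4 for genotype in H2O2. Block and estimated correlation together gave 0, 1, 1, 2 and 1 lists, flavonoid and high light in each of the last 4 and heat shock also in the bzip68 response. Deviations of same-numbered samples correlated at -0.25 to 0.49, 9 of 18 pairs above 0.1, and 9 of 12 libraries correlated best with their own number, a hint of shared sets from the data and not from the design. All 3 pairs were above 0.1 only between mock and H2O2 bzip68, and elsewhere the number was taken as a name. Other counts stayed within 1.5 times under the block.

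The odds ratio of peaks among genes changed in mock bzip68, 2.13, was 2.83 with the shorter list, 1.64 with peaks above the median score and 1.59 with the block's calls, none past the threshold, and 2.19 with promoter peaks only, 2.11 over expression strata and 1.38 with DESeq2 calls, all past it. It ran from 0.974 to 1.86 with 1 library left out, past the threshold only without mock wt replicate 3 (1.73) and at 0.974 without mock bzip68 replicate 3, where only 9 genes were called. G-box shares kept their direction in each window, shift and score range tried. Low light alternatives were not run, and the overlap rule for the peak lists could change nothing, as each peak of the shorter list has the same coordinates in the larger. Genes of few counts had wide counting intervals, and 1.5-fold changes were recovered in 3.0% to 22.4% of simulated cases.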

Other observations

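The tests of a difference between the lines, of a linked segment and of the clock were chosen only after the results were seen.

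PR1 and PR2 (BGL2), classical markers of salicylic acid defence that were named after their values were seen, differed between libraries of the wild type. PR1 had 44, 138 and 1 counts in mock wt replicates 1, 2 and 3, and 17, 0 and 157 in H2O2 wt replicates 1, 2 and 3, against 0 in all 6 bzip68 libraries. Over the groups PR1 was at least 59.1-fold lower in mock bzip68 and at least 52.5-fold lower in H2O2 bzip68 (floor of 3 counts over the group), but neither comparison passed (mock, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.655). PR2 (BGL2) had 174, 196 and 2 counts in mock wt libraries and 2, 5 and 4 in mock bzip68 libraries, and 154, 11 and 336 in H2O2 wt against 3, 12 and 2 in H2O2 bzip68. The counts of both genes were thus near those of the mutant in mock wt replicate 3 and H2O2 wt replicate 2.

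The 8 genes other than BZIP68 that changed in bzip68 under both treatments differed by up to 263-fold (MRD1 after H2O2). Loss of bZIP68 binding at these genes is argued against as their common cause, since 1 of the 8 was assigned a peak. A chromosome segment linked to BZIP68 is argued against as a cause common to all, since NDL2, AT3G05060, SADHU3-2 and AT4G16870 lie on other chromosomes. Within 5 Mb of BZIP68 lay 0 of the 8. On its chromosome, MRD1 and HEI10 lay 8.39 Mb from it and ENT1 and AT1G70340 14.9 Mb, so a longer segment stays open for these. A difference between the lines other than the BZIP68 mutation, such as a second insertion or a variant between accessions, may account for the 8 genes and stays open: 0 of the 8 had an unadjusted p under 0.05 for the difference of responses, but the labels give 1 mutant line, so line and mutation cannot be told apart. An indirect effect of the loss of bZIP68 was not tested.

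Clock genes moved in opposite directions with H2O2 by their phase. In the wild type the 5 morning genes had a median log2 fold change of -2.16 and the 5 evening genes one of 1.85, a gap of 4.0, and in bzip68 they had -1.80 and 2.27, a gap of 4.08. Harvest of the H2O2 plants at another time of day than the mock plants has the values it needs, since all 5 morning genes were lower and all 5 evening genes higher in the wild type, and it may contribute to other genes under clock control, such as COR27 and FKF1. Peroxide acting on the clock stays open too, because each treatment was sampled at a single time that the labels do not give, so both explanations cannot be told apart.

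Other splits of the same libraries were tried for each count of changed genes. The comparisons of 3 against 3 libraries allow only 10 splits, too few for a share under 0.05. The real splits called 39 (genotype, mock), 13 (genotype, H2O2), 1773 (wt response) and 1346 genes (bzip68 response), and the highest other split called 0 in each, so 1 of 10 was as large. For the response of bzip68, where same-numbered samples deviated together, 3 other splits also part all 3 pairs and called 0, and the rest part 1 pair. For the difference of responses 60 of 60 splits drawn gave at least the 0 genes of the real one, as any split must, so the count of splits decides nothing there; the highest other called 79. That split joined mock wt with H2O2 bzip68 libraries and so holds the genotype difference averaged over treatments. Its count is thus no measure of what chance gives.

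In the larger list, 932 peaks had a score of at least 300 and lay in the window of the shorter list, which leaves out some of them. Of the genes changed in mock bzip68, 34 of 39 had the same sign after H2O2 and 26 an unadjusted p under 0.05 there, and of the 13 changed after H2O2, 12 and 11 did so in mock plants. These counts hold the 9 genes called in both, and over all tested genes the log2 fold changes of both comparisons correlated only weakly (Pearson r 0.282, Spearman rho 0.119, and 0.212 and 0.115 over genes called in neither).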
